A study of Arabidopsis thaliana with 32 samples.

How the data were processed

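Transcripts of whole Arabidopsis thaliana seedlings of the Col-0 accession were measured by RNA sequencing of total RNA. Per the labels' protocols, seedlings were grown for 8 days on plates under long days (16 h light and 8 h dark at 24 °C) and were then moved to continuous light or kept in long days for 2 more days, whereas the overall design of the series speaks of 1 day. Total RNA was column-purified and treated with DNase before standard Illumina library preparation, per the labels' protocols. Whether libraries kept strand, and whether RNA was selected for poly(A) tails or depleted of ribosomal RNA, is not given in the sources used here. There were 16 libraries in continuous light and 16 in long days, sampled every 3 h from 2 h to 47 h, with 1 library per time point.

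The authors deposited 1 table per light regime with FPKM (fragments mapped to a transcript, scaled by its length and by the library's total) for each transcript and library, per the file headers. The aligner and the quantifier are not given in the sources used here, and the genome build was TAIR10 per the submitters' processing notes. Beside annotated transcripts, the tables hold transcripts assembled from the reads and merged separately in each table, so that only annotated names match between them. The continuous-light table holds 66968 transcripts, of which 53910 are annotated, 8716 are assembled at 1 locus, 1880 are assembled across several loci and 1162 lie at no annotated locus. The long-day table holds 70053, of which 53775, 10595, 3481 and 970 fall in those classes. The 2 tables share 32587 loci. Gene positions are those of the TAIR10.1 RefSeq annotation, 1-based, and symbols were taken from it by locus identifier.

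A gene's value was the sum of the FPKM of its annotated transcripts and of assembled transcripts at that locus alone. Transcripts assembled across several loci or at no locus were left out of gene values. An assembled gene that merges several loci can hold reads that belong to each of them, and 2757 loci in continuous light and 4408 in long days lie in such genes. FPKM were taken as deposited and moved to log2(FPKM + 1), on which every fold in the text is given, so folds of weakly expressed genes are understated. Genes and transcripts were tested where their mean was at least 1 FPKM. The number of reads per library is not given. Among single-exon genes the most frequent low product of FPKM and length (nt) was 22.3 to 34.4 per library, but whether this is the step of 1 read was not established. The precision of each value comes from the scatter of libraries around the fitted curve.

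Rhythms were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) by a moderated F test of a cosine and a sine term with a period of 24 h, within each table. The amplitude is that of the fitted curve, the fold is its peak to trough, and the peak time is counted in h from dawn or subjective dawn. Errors of amplitudes, peak times and differences are standard errors from these fits over 16 libraries per regime. The night contrast set the 6 libraries at 17, 20, 23, 41, 44 and 47 h, which are dark in long days, against the other 10. Differences of rhythm and of the night contrast between regimes were tested as interaction terms over all 32 libraries. There a constant offset of log2 values between the tables cancels. A loss of reads that pushes a gene's values towards the floor in 1 table flattens its curve and does not cancel. The mean level was compared in the same fit, across tables whose transcripts were merged separately. P-values were adjusted by Benjamini-Hochberg over the genes, transcripts or isoforms tested, and calls were made at an adjusted p under 0.05. With 1 library per time point there are no replicates in the usual sense. Nothing in the labels says that libraries came from separate plant cultures, so p-values measure only the spread between these libraries.

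Isoform usage was the log2 ratio of an isoform's FPKM plus 0.5 to the rest of its gene plus 0.5. It was tested the same way for isoforms with a mean share of 5 to 95% in genes with a mean of at least 1 FPKM. Intron retention was read from the reference models of annotated isoforms, since exon positions of assembled isoforms were not analysed here. Alternative 3' ends (over 50 nt from that of the gene's most abundant isoform) were read from the deposited transcript ends, for annotated and assembled isoforms alike. Poly(A) sites were not measured directly.

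The 15 gene lists were clock morning, clock evening, light harvesting, starch metabolism, phenylpropanoid and flavonoid, light signalling, dark and sugar starvation, growth hormone and elongation, cold regulated, SR splicing factors, other splicing regulators, core spliceosome, cleavage and polyadenylation, root markers and reference genes. Each list was set against the other genes tested by a two-sided Fisher's exact test, adjusted over the 15 lists per regime. That test takes genes as independent, which genes that vary together are not, so its p-values can be too small. For light harvesting genes the correlation estimated by camera in the night difference was 0.459. For interactions and levels the camera test was used with a preset correlation and again with an estimated correlation. The tests, lists, samples and the rule for genes named in the text were fixed before the data were examined. That rule took 10 clock genes in every rhythm comparison, the 8 genes of largest amplitude per regime, and the 6 largest positive and negative changes per contrast among called genes with a mean of at least 5 FPKM. It also took the 3 called members of each list with the smallest adjusted p, the 8 smallest adjusted p of a rhythm difference, and a fixed set of genes with known alternative isoforms.

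Each test across genes, transcripts or isoforms was run on simulated data, while the tests of lists and classes were not. In these data 200 features with the real means and scatter were changed by peak-to-trough sizes or effects of 0.5, 1 and 2 (log2). At size 1, 74.6% of the changed genes were recovered as rhythmic in each regime, 26.9% of transcripts in continuous light and 38.8% in long days, and 0 of 67 isoforms in each regime. At size 2, 98.5% and 90.9% of genes and 10.6% of isoforms in each regime were recovered. At size 1 the rhythm difference was recovered for 55.2% of genes and the usage difference for 0 of 67 isoforms (0 of 66 at size 2), the night contrast for 91.0% in continuous light and 79.1% in long days, its difference for 76.1% and the mean level for 98.5%. The share of calls that were false ranged from 0% to 9.72%, except 12.5% for usage in long days, where 1 of 8 calls was false. The simulated scatter was independent between features, so shifts shared by all genes of a library were absent. Far fewer features were changed than genes were called rhythmic in the real data. These shares of recovered and false calls need therefore not hold for the real libraries.

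Alternatives tried were other pseudocounts, filters and thresholds, quantile normalization, rescaling to equal library medians, a linear trend, a rank test, 12 h terms, a block per time point, and leaving out each library. Alternatives with the day as a covariate, with each cycle alone, without loci in merged assembled genes, with annotated isoforms alone, with a constant-share correction and with peak shifts under other scalings were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.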

Results

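The series asks how the circadian clock shapes transcripts, their splicing and their polyadenylation in Arabidopsis seedlings. Libraries were sampled every 3 h over 2 days in continuous light, where only the clock and the preceding light cycles can set the time, and in long days, where 8 h of darkness recur. Each regime had 16 libraries. Library totals were 578473 to 622006 FPKM in continuous light and 569534 to 587307 in long days, and the number of reads behind them is unknown. Between 42675 and 44980 transcripts per library were above 0 in continuous light, and between 44336 and 47868 in long days. Of the genes named here, LHY, TOC1, PIF4, COL9, GRP8, MEE14, DRMH1, DIN1, DIN10, BCB, XTH22, PSAD2, LHCB1.1, LHCB1.2, LHCB1.5, LHCB2.1, LHCB2.2, LHCB3, LHCA3, COR15A, COR15B, KIN2, RD29A, RS40, PRMT5, PAPS4, SQE5, IVD, U1-70K, U2AF65A, HSFA8, PTAC17, ELP, LTP1, LFNR1, HCF136, RPS15AA, AT1G07050, AT2G34585, AT5G56140 and the plastid genes ATPE, ATPB, RPL16 and RPS3 lie in merged assembled genes in at least 1 table, so their values can hold or lack reads of a neighbour.

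In continuous light the 10 clock genes examined each cycled, with peaks spread from dawn into the subjective night. The morning MYB genes LHY and CCA1 (AT2G46830, chromosome 2, 19245591 to 19248915) peaked at 1.66 ± 0.34 h and 3.07 ± 0.57 h after subjective dawn, with 10.3-fold and 8.43-fold changes from peak to trough (adjusted p = 3.64e-06 and 4.61e-04). RVE8, an activator of evening genes, peaked at 1.03 h. The pseudo-response regulators followed as PRR9 at 7.07 h, PRR7 at 8.65 h (14.5-fold) and PRR5 at 11.9 h. GI, a partner of blue-light F-box proteins, peaked at 10.4 ± 0.22 h with a 10.5-fold change. TOC1 (AT5G61380, chromosome 5, 24674963 to 24678550) peaked at 14.4 ± 0.195 h with 3.89-fold, and the evening complex genes LUX and ELF4 at 14.5 h and 16.6 h with 3.82-fold and 4.17-fold.

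**Figure D1:**
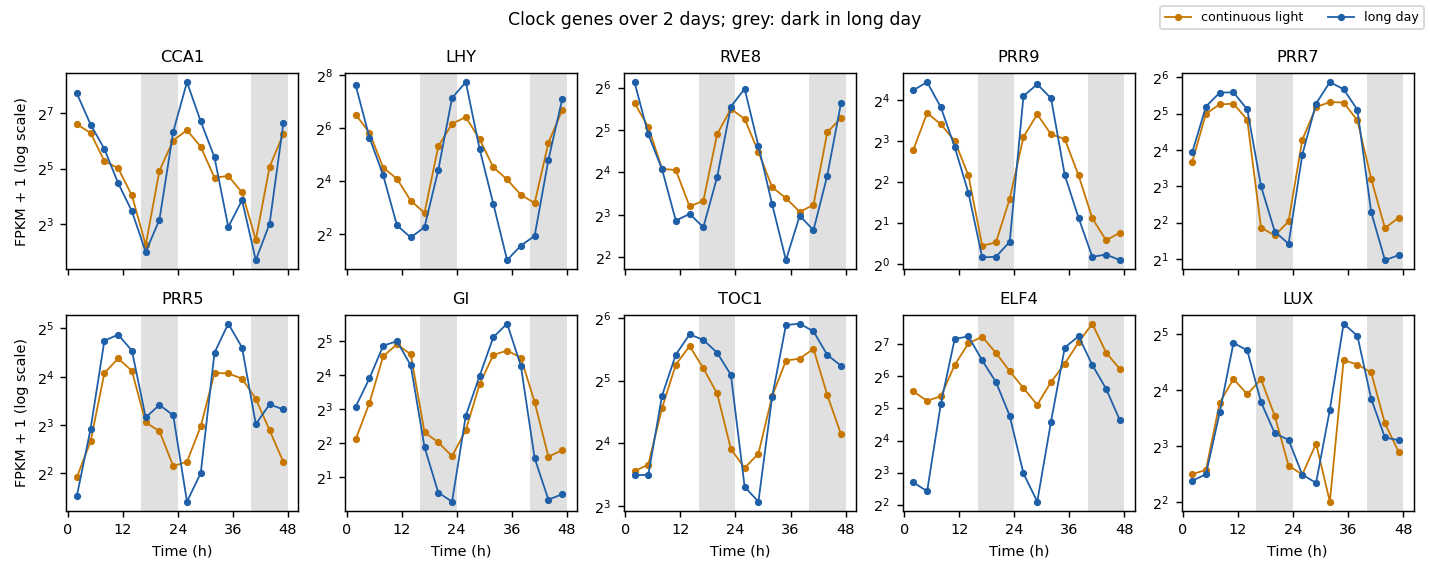
FPKM + 1 (log scale) of 10 clock genes against time in h, 1 point per library, for continuous light and long day; grey marks the hours that are dark in long day. CCA1 ranged from 3.73 to 96.1 FPKM in continuous light and from 2.25 to 276 FPKM in long day.

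In all, 5298 of 18525 genes tested (28.6%) were rhythmic in continuous light at an adjusted p under 0.05 (limma), with a median fold of 1.46 and a median peak error of 0.82 h, and 833 of them changed at least 2-fold. Among the genes of largest amplitude were FKF1, a blue-light F-box gene (15.9-fold, peak 12.04 h), CIPK20, a protein kinase gene (19.6-fold, 6.16 h), DRMH1, a dormancy-associated gene (22.9-fold, 12.9 h), MEE14 (21.6-fold, 11.5 h), AT2G15020 (26.8-fold, 23.7 h) and AT1G65490 (16.6-fold, 23.9 h). The fitted 194-fold of LHCB1.2 and 29.03-fold of LHCB1.5 are uncertain, since the LHCB1 copies are near-identical and both lie in merged assembled genes. With FPKM as deposited, 1934 rhythmic genes peaked between 12 and 16 h, against 300 to 1010 in each other 4 h window. After rescaling to equal library medians 872 of 4186 rhythmic genes peaked there (912 of 4074 after quantile normalization), and the fullest window was 20 to 24 h with 1003 genes after rescaling.

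Several gene groups of metabolism held more rhythmic members than other genes. Members of a group can vary together, so p-values of Fisher's exact test on them can be too small. Of light harvesting genes, which encode chlorophyll-binding antenna proteins, 17 of 20 tested were rhythmic (17 adjusted over the list alone; adjusted p = 9.38e-07), with a mean peak of 4.08 h. Examples were LHCB2.3 with 10.8-fold at 3.74 h, LHCB4.2 with 3.39-fold and LHCB6 with 3.25-fold. Starch genes were rhythmic in 20 of 23 (20 adjusted over the list alone; adjusted p = 1.34e-07), with the phosphorylase PHS1 at 11.4 h, the disproportionating enzyme DPE1 at 12.6 h and the beta-amylase BAM3 (AT4G17090) at 18.1 h (5.01-fold). Phenylpropanoid and flavonoid genes were rhythmic in 17 of 19 (17 adjusted over the list alone; adjusted p = 2.57e-07) and peaked late in the subjective night at a mean of 22.9 h. Chalcone synthase CHS changed 6.30-fold with a peak at 23.7 h, flavonol synthase FLS1 6.43-fold at 22.97 h and chalcone isomerase CHI 3.58-fold at 23.1 h. Light signalling genes were rhythmic in 17 of 19 (18 adjusted over the list alone; adjusted p = 2.57e-07), among them the blue-light receptor gene CRY2 (1.42-fold), the flowering repressor CDF2 (2.32-fold) and the bHLH gene PIF5 (5.19-fold at 5.53 h).

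Genes that respond to darkness or sugar starvation cycled in constant light, in 15 of 18 (17 adjusted over the list alone; adjusted p = 5.54e-06) with a mean peak of 11.2 h. The asparagine synthetase gene ASN1 changed 14.5-fold with a peak at 8.88 ± 0.27 h, the dormancy gene DRM1 5.50-fold at 13.4 h and TPS11, of the trehalose phosphate synthase family, 2.74-fold at 10.2 h. Of growth hormone and elongation genes 8 of 10 were rhythmic (8 adjusted over the list alone; adjusted p = 0.00210), with the auxin gene IAA29 at 5.84-fold, the expansin gene EXPA8 at 3.85-fold and the homeobox gene ATHB2 at 2.15-fold. Clock morning and evening genes were rhythmic in 13 of 14 and 13 of 15 (the same counts adjusted over the lists alone; adjusted p = 2.62e-06 and 1.03e-05), at mean peaks of 4.14 h and 13.8 h. Cold-regulated genes were rhythmic in 4 of 9 (5 adjusted over the list alone; adjusted p = 0.392), among them COR15B (11.1-fold), COR15A (5.86-fold) and CBF3 (3.41-fold). Root markers (3 of 17, 1 adjusted over the list alone) and reference genes (3 of 10, 3 adjusted over the list alone) did not differ from other genes in the share of rhythmic members (adjusted p = 0.532 and 1). The reference genes EF1A, SAND and ACT2 changed 1.35-fold, 1.26-fold and 1.26-fold, and 0 of the 10 were rhythmic after rescaling to equal medians.

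In long days every one of the 10 clock genes was again rhythmic, and most fitted amplitudes were larger. LHY changed 74.2-fold with a peak at 1.25 ± 0.22 h, CCA1 36.4-fold at 3.47 ± 0.40 h, GI 33.0-fold at 9.24 ± 0.23 h and PRR7 27.9-fold at 8.99 h (adjusted p = 4.58e-07, 4.61e-05, 4.58e-07 and 2.45e-06). PRR9 changed 24.9-fold at 6.21 h, ELF4 24.8-fold at 14.9 h, RVE8 10.8-fold at 1.42 h, PRR5 5.95-fold at 12.5 h, TOC1 5.55-fold at 15.6 h and LUX 5.28-fold at 13.4 h. LNK1 and LNK2, coactivators that bind RVE8, changed 45.7-fold and 26.6-fold with peaks at 6.89 h and 4.995 h. The histone demethylase gene JMJD5 changed 18.1-fold at 16.9 h, and the flowering repressor CDF3 17.1-fold at 6.49 h.

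Rhythmic genes numbered 6034 of 18801 tested (32.1%) in long days, with a median fold of 1.48, and 1108 of them changed at least 2-fold. With FPKM as deposited 2477 of them peaked between 16 and 20 h in the early night. After rescaling to equal library medians 770 of 4098 peaked there (858 of 4136 after quantile normalization), with 565 to 811 in the other windows after rescaling. The size of the crowding at dusk and early night in both regimes thus depended on the scaling of the libraries. After quantile normalization 12 to 16 h in continuous light and 16 to 20 h in long days were still the fullest windows, though the next held 848 and 824 genes.

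**Figure D2:**
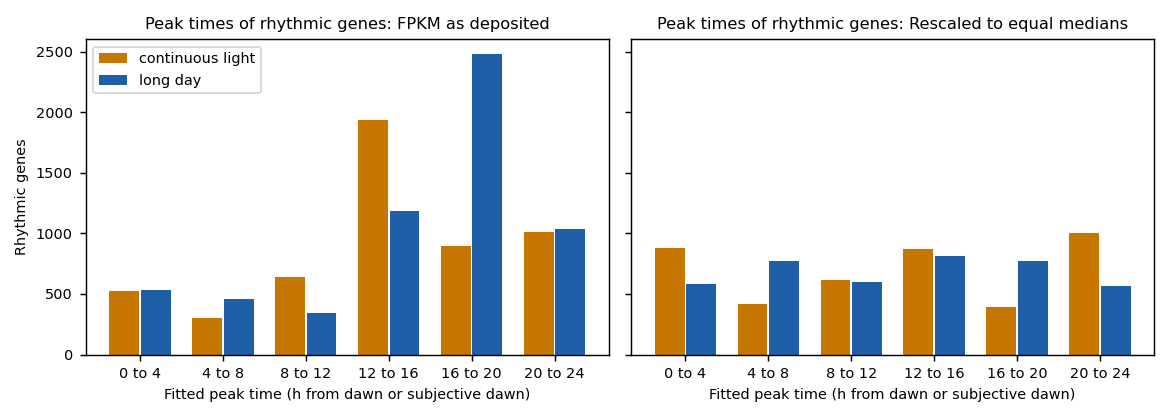
Number of rhythmic genes by fitted peak time in 4 h windows, for continuous light and long day, with FPKM as deposited (left) and after rescaling libraries to equal medians (right). The window from 16 to 20 h holds 2477 long-day genes as deposited and 770 after rescaling.

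Light harvesting, starch, clock and light signalling genes were the groups with more rhythmic members than other genes in long days. Light harvesting genes were rhythmic in 15 of 20 (16 adjusted over the list alone; adjusted p = 3.83e-04) with a mean peak of 7.76 h, among them LHCB2.3 (44.4-fold at 6.24 h), LHCA4 (13.7-fold at 7.79 h) and LHCA1 (11.99-fold at 7.47 h). LHCB1.1 (46.2-fold), LHCB1.5 (256-fold) and LHCB2.2 (33.4-fold) lie in merged assembled genes and share reads with near-identical copies, so their folds are uncertain. Starch genes were rhythmic in 18 of 23 (19 adjusted over the list alone; adjusted p = 5.34e-05), with the debranching enzyme ISA3 at 12.9 h, the starch synthase SS4 at 12.4 h and the phosphatase SEX4 at 12.9 h. Clock morning genes were rhythmic in 12 of 14 and evening genes in 14 of 15 (the same counts adjusted over the lists alone; adjusted p = 2.68e-04 and 1.92e-05), at mean peaks of 4.25 h and 15.6 h. Light signalling genes were rhythmic in 12 of 19 (15 adjusted over the list alone; adjusted p = 0.0177), with PIF5 at 4.74-fold and SPA1, a partner of COP1, at 2.52-fold.

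Starvation genes were rhythmic in 10 of 18 (11 adjusted over the list alone; adjusted p = 0.0909), at a mean peak of 18.0 h, with the BTB gene BT2 at 8.95-fold, the branched-chain aminotransferase BCAT2 at 4.94-fold and TPS9 at 2.15-fold. Phenylpropanoid genes were rhythmic in 7 of 17 (7 adjusted over the list alone; adjusted p = 0.647), with PAL2, the first enzyme of the pathway, at 1.84-fold, CHS at 3.09-fold and 4CL3 at 2.26-fold. Growth hormone genes were rhythmic in 2 of 10 (IAA29 and the brassinosteroid gene BR6OX2; 2 adjusted over the list alone; adjusted p = 0.647), and in 5 of 10 after either quantile normalization or rescaling to equal medians. Cold-regulated genes were rhythmic in 2 of 8 (RD29A and KIN2; 2 adjusted over the list alone; adjusted p = 1), root markers in 2 of 18 (SCR and the sodium transporter HKT1; 2 adjusted over the list alone; adjusted p = 0.140) and reference genes in 2 of 10 (ACT2 and TIP41; 2 adjusted over the list alone; adjusted p = 0.647).

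**Figure D3:**
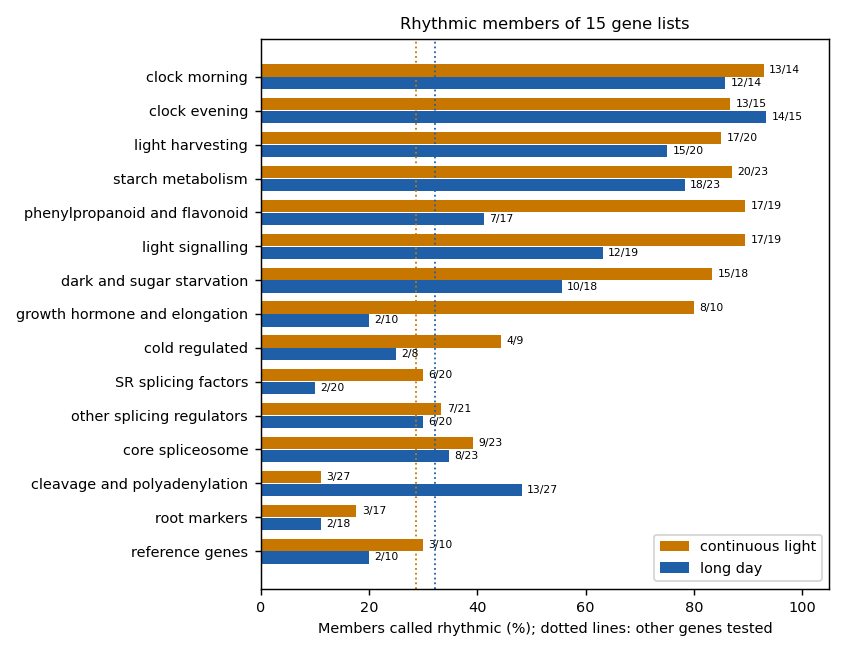
Percent of tested members of 15 gene lists called rhythmic in continuous light and in long day, with counts beside the bars; dotted lines mark the other genes tested. Starch metabolism stands at 87.0% and 78.3%, cleavage and polyadenylation at 11.1% and 48.1%.

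The regimes were then compared gene by gene. Of the clock genes, LHY, GI and ELF4 differed in rhythm (interaction adjusted p = 0.00153, 0.00211 and 6.52e-04, limma), each with a larger amplitude in long days. The amplitude (log2) was 1.68 ± 0.15 against 3.11 ± 0.18 for LHY, 1.69 ± 0.10 against 2.52 ± 0.15 for GI and 1.03 ± 0.06 against 2.32 ± 0.21 for ELF4. For CCA1, RVE8, PRR9, PRR7, PRR5, TOC1 and LUX the interaction did not pass (adjusted p = 0.0795 to 0.794). Light harvesting genes differed in 13 of 20 tested (16 adjusted over the list alone), with LHCB2.3 peaking at 6.24 h in long days and 3.74 h in continuous light (adjusted p = 2.64e-04). Starvation genes differed in 13 of 18 (17 adjusted over the list alone): ASN1 cycled in continuous light and had a 2.08-fold fitted change in long days (rhythm adjusted p = 0.147, interaction 3.28e-04). DIN1, a senescence and dark-induced gene, peaked at 9.44 h in continuous light and at 18.0 h in long days. Phenylpropanoid genes differed in 7 of 18, evening clock genes in 6 of 15 and starch genes in 5 of 23 (12, 11 and 8 adjusted over the lists alone).

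The smallest adjusted p values of a rhythm difference outside these groups belonged to genes with shifted or newly large rhythms. AT2G15020 peaked at 23.7 ± 0.21 h in continuous light and 4.00 ± 0.45 h in long days (adjusted p = 6.73e-05), and NDA1, a mitochondrial NADH dehydrogenase gene, at 23.9 h and 4.60 h. AT2G23910 peaked at 20.2 h and 16.6 h. ACBP3, an acyl-CoA-binding protein gene, changed 1.28-fold in continuous light and 3.80-fold in long days, and ATR2, a P450 reductase gene, 1.19-fold and 2.07-fold (adjusted p = 8.96e-05 for each of these 4). The 2 smallest, for the heat shock factor gene HSFA8 and for PTAC17, come from loci listed at 0 in every long-day library that lie in merged assembled genes, and are no evidence of a changed rhythm.

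Across genes, 1421 of 18801 (7.56%) differed in rhythm, and 1045 of these had the larger amplitude in long days. Of 18130 genes tested in both tables, 2655 were rhythmic in both, against 1704.3 from lists that are independent of each other. Their peaks came a median of 1.303 h later in long days (quartiles -0.30 and 3.06 h), and 1833 (69.0%) peaked within 3 h of each other, against 28.9% over all pairings of a peak in 1 regime with a peak in the other. Under rescaling to equal medians 1856 were rhythmic in both, against an expected 912.5, with a median shift of 1.11 h. Genes are not replicates of each other, and each table's libraries share their own errors.

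During the dark hours of long days, more antenna genes fell than rose, and more genes of dark and sugar starvation rose than fell. LHCB3 fell by 3.50 ± 0.42 (log2, 6 night against 10 day libraries; adjusted p = 1.12e-04) and LHCA4 fell by 2.67 ± 0.26, and of 20 light harvesting genes 13 fell, 1 rose and 6 did not pass (14 adjusted over the list alone). The clock genes LNK1, PRR7 and GI fell by 4.19 ± 0.38, 3.37 ± 0.35 and 3.43 ± 0.39, and the growth regulator PIF4 fell by 3.27 ± 0.32. The largest rises were those of RVE2, a MYB gene of the CCA1 family (3.36 ± 0.61), COL9, a B-box flowering repressor (2.55 ± 0.54), EXL1 (AT1G35140; 2.34 ± 0.41), BBX20 (2.196 ± 0.28) and POX1, which encodes proline dehydrogenase (2.17 ± 0.28), beside AT2G34585, in a merged assembled gene (2.96 ± 0.95). Of 18 starvation genes 8 rose and 0 fell (11 adjusted over the list alone; 10 did not pass), among them BT2 (2.07 ± 0.37), TPS9 (0.86 ± 0.11) and DIN3, of branched-chain amino acid breakdown (0.47 ± 0.08); after rescaling to equal medians 7 rose and 1 fell.

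Night and day differed in long days for 3131 genes (limma), of which 2620 were higher at night and 511 lower. The share higher was 83.7% with FPKM as deposited, 61.0% (1210 of 1984) after quantile normalization and 57.2% (1126 of 1968) after rescaling to equal medians. Without the library at 44 h, 1970 genes passed.

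In continuous light the same hours separated fewer genes, and more starvation genes fell than rose. ASN1 fell by 2.71 ± 0.28 in the subjective night (adjusted p = 9.63e-05), DIN1 fell by 1.69 ± 0.29 and TPS8 fell by 0.71 ± 0.10; of 18 starvation genes 6 fell, 1 rose and 11 did not pass (10 adjusted over the list alone). PRR7, PRR9 and PIF4 fell by 2.77 ± 0.26, 2.18 ± 0.24 and 2.64 ± 0.22, and CIPK20 fell by 2.65 ± 0.44. BAM3 rose by 1.51 ± 0.25, FLS1 by 1.398 ± 0.38, and SQE5, a squalene epoxidase gene, by 1.26 ± 0.27. Of 19 phenylpropanoid genes 7 rose and 12 did not pass (14 adjusted over the list alone), among them the flavonol regulators MYB111 and MYB12; after rescaling to equal medians 2 rose. Light harvesting genes fell in 5 of 20 and rose in 1 (9 adjusted over the list alone), with LHCA3 and LHCA1 falling by 1.22 ± 0.23 and 1.42 ± 0.30. In all 852 genes passed, 611 higher and 241 lower (71.7% higher), against 292 and 314 (48.2% higher) after quantile normalization and 382 and 280 (57.7% higher) after rescaling. The count was 508, 413 and 392 without the libraries at 17, 20 and 44 h.

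The largest positive differences of the night contrast between regimes included genes induced by darkness. ASN1 (AT3G47340, chromosome 3, 17437840 to 17441431) differed by 2.99 ± 0.46 (log2, long day minus continuous light; adjusted p = 1.45e-04), DIN1 by 2.95 ± 0.42, AT3G15450 by 2.67 ± 0.60, DIN10, a raffinose synthase family gene, by 2.65 ± 0.51, the blue copper protein gene BCB by 2.33 ± 0.67 and the cell wall enzyme gene XTH22 by 2.296 ± 0.53. The largest negative differences were those of AT3G28270 (-3.76 ± 0.87), AT2G15020 (-3.34 ± 1.03), NDA1 (-3.07 ± 0.80), PSAD2, a photosystem I subunit gene (-2.27 ± 0.61), LHCB2.1 (-2.18 ± 0.65) and LNK1 (-2.13 ± 0.53). Of 18 starvation genes 11 were higher and 0 lower (14 adjusted over the list alone), with a median of 1.06; camera gave an adjusted p = 6.07e-12, and adjusted p = 0.0897 with an estimated correlation. Light harvesting genes were lower in 6 of 20 and higher in 0 (10 adjusted over the list alone), with a median of -0.91 (camera adjusted p = 5.86e-08; adjusted p = 0.397 with an estimated correlation). Both directions held under quantile normalization and rescaling to equal medians.

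For phenylpropanoid genes camera gave an adjusted p = 4.45e-05 downward with 0 of 18 members called by limma (0 adjusted over the list alone; adjusted p = 0.630 with an estimated correlation), and for morning clock genes 0.0429 with 1 of 14 called (2 adjusted over the list alone; adjusted p = 0.724 with an estimated correlation). Over all genes 1116 passed, 852 more positive in long days and 264 more negative (76.3%), against 67.2% of 938 after quantile normalization and 60.9% of 952 after rescaling. Without the long-day library at 44 h, 706 genes passed.

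**Figure D4:**
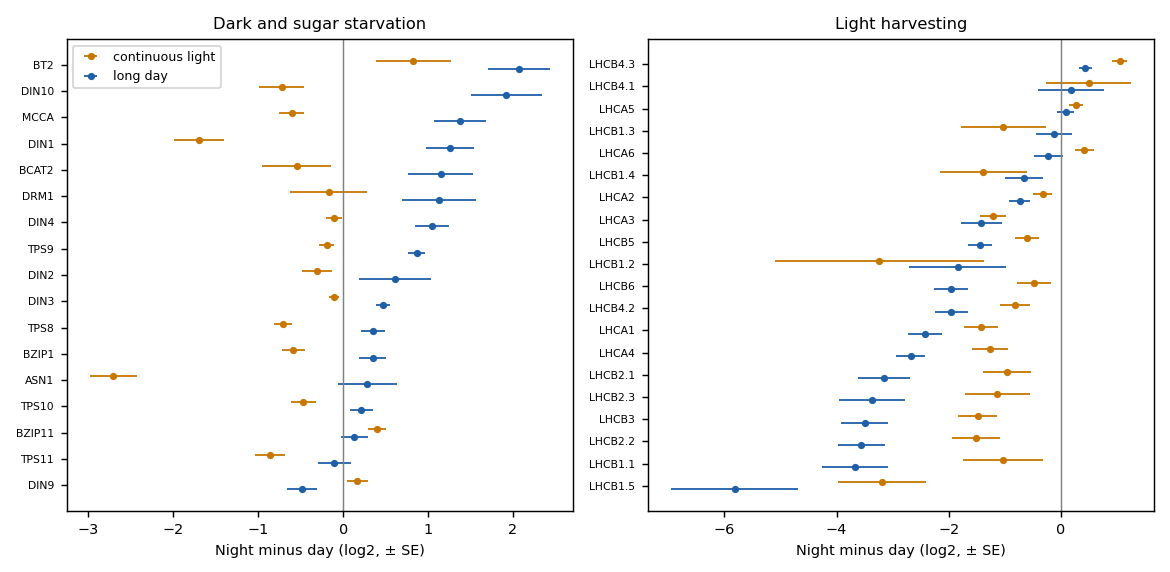
Night minus day (log2, points with standard errors from limma, 6 against 10 libraries) for members of the starvation and light harvesting lists in continuous light and long day. ASN1 stands at -2.71 in continuous light and 0.28 in long day, and LHCB3 at -1.49 and -3.50.

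The mean level was compared across the tables, which differ in their assembled transcripts and possibly in library batch, so regime and table cannot be told apart. Antenna genes were lower in long days, in 17 of 20 light harvesting genes with 1 higher (18 adjusted over the list alone; median -1.12), for example LHCB5 (-1.54 ± 0.08), LHCB4.2 (-1.38 ± 0.10) and LHCA2 (-1.01 ± 0.08). Flavonoid genes were lower in 14 of 18 and higher in 0 (14 adjusted over the list alone; median -1.02), with CHS at -1.49 ± 0.16 and the anthocyanin gene LDOX at -1.50 ± 0.16. Starch genes were lower in 15 of 23 and higher in 1 (18 adjusted over the list alone; median -0.34), with the ADP-glucose pyrophosphorylase genes APS1 (AT5G48300) and APL1 at -0.88 ± 0.06 and -0.74 ± 0.06. Starvation genes were higher in 16 of 18 and lower in 1 (18 adjusted over the list alone; median 1.07), with ASN1 at 2.18 ± 0.18, TPS11 at 1.44 ± 0.09 and the transcription factor gene BZIP1 at 1.39 ± 0.08. These directions held under both other scalings. Camera gave adjusted p = 4.28e-11, 9.50e-08, 8.17e-07 and 9.01e-04 for these lists, and adjusted p = 0.0570, 0.114, 0.0570 and 0.418 with an estimated correlation.

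Cleavage and polyadenylation genes were higher in 20 of 27 and lower in 2 (22 adjusted over the list alone; median 0.25), with the poly(A) polymerase genes PAPS4 at 0.66 ± 0.05 and PAPS1 at 0.46 ± 0.04 (camera adjusted p = 0.0138; adjusted p = 0.546 with an estimated correlation). After rescaling to equal medians 15 were higher and 2 lower. SR splicing factor genes were higher in 12 of 20 and lower in 1 (13 adjusted over the list alone), for example RS31 (0.56 ± 0.05), and 10 were higher after rescaling. This list did not pass by camera (adjusted p = 0.0902, and 0.546 with an estimated correlation). Reference genes were likewise higher in 6 of 10 and lower in 2. In all 11851 of 18801 genes differed, 8230 higher and 3621 lower in long days (69.4% higher), against 56.7% of 10758 after quantile normalization and 49.7% of 10640 after rescaling. The median of all genes was 0.12 as deposited, 0.035 after quantile normalization and -0.0035 after rescaling.

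Plastid-encoded transcripts were far higher in the long-day libraries. The ATP synthase genes ATPE and ATPB differed by 8.17 ± 0.16 and 8.11 ± 0.19 (log2), and the ribosomal protein genes RPL16, RPS19 and RPS3 and the gene YCF1.2 by 6.61 to 7.38. The plastid share of all FPKM was 1.75 to 2.32% in long days and 0.0127 to 0.0927% in continuous light. The largest falls, those of ELP, LTP1, LFNR1 and HCF136, lay in merged assembled genes, and RPS15AA (AT5G59850), AT5G56140 and, among starvation genes, IVD were listed at 0 in every long-day library.

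**Figure D5:**
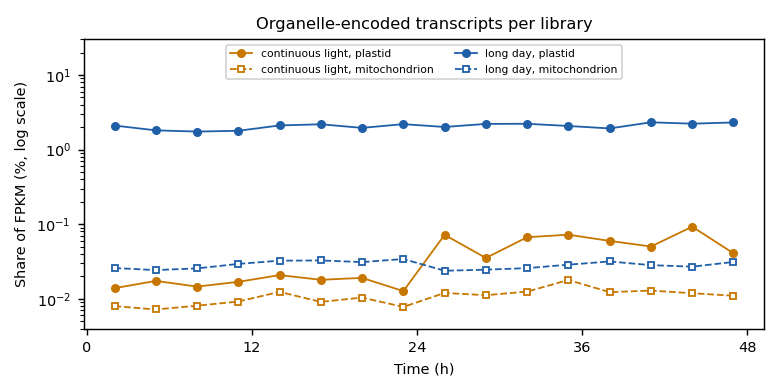
Share of library FPKM (%, log scale) from plastid and mitochondrial transcripts against time in h, 1 point per library. The plastid share is 0.0127 to 0.0927% in continuous light and 1.75 to 2.32% in long day, and the mitochondrial share 0.0072 to 0.0179% and 0.0238 to 0.0342%.

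None of the 4 lists of genes whose products process RNA differed from other genes in its share of rhythmic members. GRP7, which regulates splicing and is a clock output, changed 9.70-fold in continuous light (peak 12.9 ± 0.32 h) and 13.9-fold in long days (13.9 ± 0.45 h), and its relative GRP8 3.22-fold and 3.10-fold. Other splicing regulators were rhythmic in 7 of 21 in continuous light and 6 of 20 in long days (8 and 9 adjusted over the list alone; adjusted p = 0.730 and 1), including the methyltransferase gene PRMT5 (1.53-fold and 1.42-fold) and the SR kinase gene SRPK2 (1.46-fold and 1.66-fold). SR splicing factors were rhythmic in 6 of 20 and 2 of 20 (8 and 1 adjusted over the list alone; adjusted p = 1 and 0.0806), with RS40 at 1.70-fold in continuous light and RS31A at 1.44-fold and 1.43-fold. Core spliceosome genes were rhythmic in 9 of 23 and 8 of 23 (9 and 10 adjusted over the list alone; adjusted p = 0.385 and 0.951), among them MAC3B and CDC5, of the complex around Prp19, at 1.45-fold and 1.42-fold in continuous light and the Sm-like gene LSM5 at 1.57-fold in long days. Cleavage and polyadenylation genes were rhythmic in 3 of 27 and 13 of 27 (2 and 13 adjusted over the list alone; adjusted p = 0.0885 and 0.161). They included PABN3, a nuclear poly(A)-binding protein gene (1.38-fold in each regime), PAPS2 (1.38-fold in continuous light), and CSTF64 and CPSF73-II (1.51-fold and 1.59-fold in long days). After rescaling to equal medians 4 of the 27 were rhythmic in long days, and core spliceosome genes were rhythmic in 3 of 23 in continuous light and 2 of 23 in long days (3 and 4 after quantile normalization). SR splicing factors were then rhythmic in 4 of 20 in continuous light and other splicing regulators in 4 of 20 in long days, under either scaling. For cleavage and polyadenylation genes the rhythm differed between regimes for 1 of 27.

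Single transcripts were then tested. In continuous light 3049 of 27954 transcripts were rhythmic and in long days 2981 of 29968. Of 141 and 135 genes with at least 2 rhythmic transcripts, the peaks lay within 3 h of each other in 118 and 118, and over 6 h apart in 18 and 9.

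Isoform usage asks whether splicing or 3' end choice moves apart from the gene's own rhythm. In long days 2 isoforms of 1 gene passed, those of AT1G07050, a gene with a CCT motif (chromosome 1, 2163575 to 2165261), with adjusted p = 0.00214. Usage of its second isoform peaked at 3.40 ± 0.36 h and that of its first at 15.4 ± 0.38 h, each with an amplitude of 1.92 (log2). With mean shares of 9.31% and 90.7% these isoforms make up the gene. Their log ratios therefore mirror each other, and the 2 calls are 1 observation. The gene averaged 4.48 FPKM and lies in a merged assembled gene. Its call ends when usage is taken as a share, after a constant-share expectation is subtracted and with either cycle alone, and the filters on merged loci, on shares of 10 to 90% and on gene means of at least 5 leave 0 calls. The 2 calls stay with a pseudocount of 0.1, with a linear trend, with the day as a covariate and among annotated isoforms alone. In 12 of 100 orders of the time labels, the real one included, at least 2 isoforms passed. In continuous light 0 of 23290 isoforms passed (limma, 1221 or 5.24% at an unadjusted p under 0.05, smallest adjusted p = 0.0731). In long days 1429 of 25286 (5.65%) were under an unadjusted p of 0.05. The difference between regimes passed for 0 of 14481 (limma, 768 or 5.30% at an unadjusted p under 0.05, smallest adjusted p = 0.519), though 0 of 66 simulated differences of 2 (log2, peak to trough) were recovered, so this 0 says little. In continuous light 1 isoform passed without the library at 5 h and 2 without that at 14, 35 or 47 h. In long days 11 passed without the library at 2 h and 4 without that at 11 or 23 h, and 2 passed for the difference without the continuous-light library at 32 h.

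Among 17 genes with known alternative isoforms, 0 of 61 isoforms passed over all isoforms in continuous light and 0 of 57 in long days (limma, 14 and 19 at an unadjusted p under 0.05), while 6 and 12 passed adjusted over the list alone. In continuous light these were 2 isoforms of GRP7, 2 of PRR9, 1 of LNK2 and 1 of PRR7. The 2 of GRP7 make up the gene, so their log ratios mirror each other and are 1 observation. GRP7's annotated first isoform, at a mean share of 72.2%, had a usage amplitude of 0.60 ± 0.15 (log2) with its highest usage at 23.2 h (adjusted p = 0.0396 over the list alone). Its share amplitude of 7.58 ± 1.94 percentage points did not pass (adjusted p = 0.144 over the list alone). In long days the 12 were 4 isoforms of PRR9, 2 of RVE8, 1 of JMJD5, 1 of LNK2 and 4 of PRR7. RVE8's AT3G09600.1, at a mean share of 11.3%, had a usage amplitude of 1.95 ± 0.30 (log2) with its highest usage at 14.2 h (adjusted p = 5.44e-04 over the list alone), away from the gene's own peak, and a share amplitude of 18.7 ± 3.48 points (adjusted p = 0.00573 over the list alone). That isoform's own level, at a mean of 2.56 FPKM, was not called rhythmic (limma, adjusted p = 0.693), while its gene was. This usage rhythm thus does not show that the isoform itself cycled. For PRR9 a constant share would give 75.1 to 104% of the usage amplitude through the pseudocount, so its calls are no evidence of a change in usage. Its share as a fraction decides nothing in long days, since the gene lay at 0.0673 to 0.173 FPKM at 17, 20, 41, 44 and 47 h. CCA1, LHY, TOC1, GRP8, RVE2, FLM, SR30, RS31, RS2Z33, U1-70K and U2AF65A had 0 isoforms that passed as a log ratio over the list alone in either regime. With usage as a share, 0 of 61 passed over the list alone in continuous light and 8 of 57 in long days, 3 of RVE8, 2 of PRR9 and 1 each of LHY, LNK2 and PRR7. Those of LHY and PRR7, both assembled transcripts, had share amplitudes of 34.4 ± 6.99 and 42.4 ± 7.16 points (adjusted p = 0.00678 and 0.00573 over the list alone), and that of LHY did not pass as a log ratio (adjusted p = 0.242 over the list alone).

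Annotated isoforms that retain an intron were set against the other annotated isoforms. Isoforms with a distant 3' end, annotated or assembled, were set against those with a nearer one, leaving out each gene's most abundant isoform. With 0 calls in continuous light and 1 mirrored pair in long days, the planned comparison had almost nothing to compare. Fisher's exact test gave p = 1 for both classes in continuous light, and 0.552 for retained introns and 0.419 for 3' ends in long days. At an unadjusted p under 0.05, retained-intron isoforms made up 376 of 5799 (6.48%) in long days against 655 of 11735 others (5.58%; p = 0.0185), and 286 of 5551 (5.15%) in continuous light against 591 of 11101 (5.32%; p = 0.659). For gene means of at least 5 FPKM the shares were 6.73% against 5.39% in long days (Fisher's exact test, p = 0.00315). In continuous light they were 5.35% against 5.19% (p = 0.723). For 3' ends over 50 nt away the shares were 5.74% against 5.60% in long days (p = 0.706) and 5.58% against 5.04% in continuous light (p = 0.158). These p-values are not adjusted, and they take isoforms as independent, though isoforms of 1 gene have linked ratios. Nor were the ratios corrected for a constant share seen through the pseudocount. With that correction 1281 rather than 1429 of 25286 long-day isoforms were under an unadjusted p of 0.05 (limma), and the classes were not compared again. Isoform ratios had a residual SD of 0.94 and 0.98 (log2) against 0.18 and 0.20 for genes. Rhythms of usage of 2 (log2) peak to trough or less were therefore rarely detectable, with 7 of 66 simulated rhythms of size 2 recovered in each regime.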

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

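The interaction and camera tests were planned, while the exchanges of libraries between regimes and the test of merged assembled genes were chosen after the results were seen.

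Darkness-induced genes and antenna genes were among those whose night contrast differed between regimes. In the night contrast, the asparagine synthetase gene ASN1, the dark-induced DIN1, AT3G15450, the raffinose synthase family gene DIN10, the blue copper protein gene BCB and the cell wall enzyme gene XTH22 differed by 2.99, 2.95, 2.67, 2.65, 2.33 and 2.296 (log2, long day minus continuous light). AT3G28270, AT2G15020, the NADH dehydrogenase gene NDA1, the photosystem I gene PSAD2, the antenna gene LHCB2.1 and the clock coactivator LNK1 differed by -3.76, -3.34, -3.07, -2.27, -2.18 and -2.13. By camera, starvation genes moved up (adjusted p = 6.07e-12), and light harvesting, phenylpropanoid and morning clock genes moved down (adjusted p = 5.86e-08, 4.45e-05 and 0.0429). None of these 4 passed with an estimated correlation (adjusted p = 0.0897, 0.397, 0.630 and 0.724). ASN1 fell in the subjective night of continuous light and not in the night of long days, where its contrast was 0.28 ± 0.35.

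The rhythm itself differed between regimes for 1421 genes and the night contrast for 1116 (limma). Among clock genes LHY, GI and ELF4 had interaction adjusted p values of 0.00153, 0.00211 and 6.52e-04. AT2G15020 (adjusted p = 6.73e-05) and ACBP3, AT2G23910, NDA1, DIN1 and ATR2 (adjusted p = 8.96e-05 each) had the next smallest values after HSFA8 and PTAC17. DIN1, DIN10, BCB, XTH22, PSAD2 and LHCB2.1 also lie in merged assembled genes, though they are above 0 in every library. In 100 exchanges of the regime within time points with the mean of each table removed, the real one included, 1 rhythm count and 1 night count were as large as the real ones, and the highest others were 148 and 533 genes. Exchanges with the table means kept had been run first, and 9 and 8 of 100 were as large, with up to 8276 and 9655 genes. Those exchanges carry the differences in mean level between the tables into the time terms, and the version without table means was added after seeing them.

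The heat shock factor gene HSFA8 (adjusted p = 1.57e-07) and the plastid-chromosome protein gene PTAC17 (4.78e-05) were listed at 0 in every long-day library. They belong to a wider pattern, in which 65 nuclear loci had a mean level at least 8-fold lower in long days. Of these, 93.9% lay in genes merged in the long-day assembly, against 17.1% of the other loci tested (Fisher's exact test, two-sided, p = 8.67e-42), and 23 of 37 loci at least 8-fold higher in long days also lay in such genes. Values given to assembled transcripts that span several loci are therefore a candidate explanation for these falls, though merged genes hold many of the large changes in either direction. For the 4 loci outside merged genes lower expression in long days stays open, and for those inside the regimes cannot be told apart from the assembly.

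Some signal lies in transcripts that the gene values leave out. Assembled transcripts that span several loci held up to 2.59% of the FPKM of a library in continuous light and up to 4.82% in long days. Assembled transcripts at no annotated locus held up to 0.59% and 0.747%. No control libraries exist against which to set these shares.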

How the results depend on the processing

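The tests with the day as a covariate, with 1 cycle alone, without merged loci, with annotated isoforms alone, with the constant-share correction and with peak shifts under other scalings were chosen after the data were seen, and the others were planned.

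Counts of genes that differ in mean level stayed within 1.5 times under each alternative, from 9027 to 13307. Under a pseudocount of 0.1, other filters, a linear trend or a rank test, the counts of rhythmic genes and transcripts also stayed within 1.5 times. In the lists below, a count is given where it moved further; the cause was not tested, except that thresholds and single cycles of 8 libraries lower a count by construction. With adjusted p under 0.01, 2874 genes and 1583 transcripts were rhythmic in continuous light and 2919 and 1133 in long days. With a peak-to-trough of at least 1 (log2) these were 833, 969, 1108 and 1131. With 12 h terms added, 3295 genes and 1734 transcripts were rhythmic in continuous light. With the first cycle alone 1864 and 575 passed in continuous light and 415 and 0 in long days, and with the second alone 2719, 789, 501 and 2. Beside the 0 transcripts, limma gave 4280 at an unadjusted p under 0.05.

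Rhythm differences numbered 2243 with the day as a covariate, 0 with the first cycle alone (limma, 2241 at an unadjusted p under 0.05) and 134 with the second. Night differences numbered 10 and 194 with the first and second cycle alone. Night calls in long days numbered 1984 after quantile normalization, 1968 after rescaling to equal medians, and 41 and 119 with the first and second cycle alone. Those in continuous light numbered 1307 with the day as a covariate, and 7 and 10 with single cycles. Rhythmic usage in long days was called for 0 isoforms with a share of 10 to 90%, with gene means of at least 5, with usage as a share, with either cycle alone, without merged loci and after the constant-share correction, and for 6 with annotated isoforms alone; beside these counts of 0, limma gave 1064 to 1424 at an unadjusted p under 0.05. The lists passing stayed at 8 in continuous light and went from 5 to 6 in long days at adjusted p under 0.01. The list added in long days was that of starvation genes (7 of 18 rhythmic, Fisher's exact test, adjusted p = 0.0354). The median peak shift between regimes ranged from 1.11 h (rescaling to equal medians) to 1.61 h.

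Leaving out 1 library at a time gave 706 (without the long-day library at 44 h) to 1460 night differences, 1970 (without 44 h) to 3408 night calls in long days and 392 to 1079 in continuous light, where the count was 508, 413 and 392 without 17, 20 and 44 h. Usage calls ranged from 0 to 2 in continuous light, 2 to 11 in long days (11 without 2 h) and 0 to 2 for the difference. The other counts stayed within 1.5 times, with 4469 to 5733 rhythmic genes in continuous light, 4922 to 6234 in long days and 995 to 1746 rhythm differences.

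Libraries of the same hour in the 2 regimes share only a number: their deviations correlated at -0.134 to 0.089, and 2 of 16 correlated best with their own number. With the hour as a block, 1809 night differences, 1121 rhythm differences, 11384 level differences and 0 usage differences were called.

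For the genes named in the text, outcomes were counted per gene, comparison and setting. Leaving out 1 library left 5772 outcomes unchanged, while 307 calls were lost and 1 was gained. With 1 cycle alone 287 outcomes stayed and 277 calls were lost. Under the other settings 2132 outcomes stayed, 79 calls were lost and 1 was gained. Unchanged outcomes include clock genes whose rhythm difference was not called in either fit. No call reversed, though reversal was not examined for rhythm differences. Reads per library are not given, and how far depth limits the isoform ratios was not measured.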

Other observations

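The name groups, the orders and splits of libraries, the organelle test and the constant-share tests were chosen after the results were seen, while the tests of cycle shift and of class means were written before their results.

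With FPKM as deposited, B-box genes, zinc-finger transcription factors of light and flowering responses, were rhythmic more often than other genes in both regimes. Other scalings were not run for the name groups, and Fisher's exact test takes their genes as independent. Of 26 tested, 23 were rhythmic in continuous light and 21 in long days (Fisher's exact test adjusted over 32 tests, p = 9.68e-09 and 7.19e-06), with median folds of 4.33 and 7.94, and 10 differed in rhythm between regimes. BBX16 changed 11.1-fold with a peak at 2.61 h in continuous light and 25.9-fold at 6.03 h in long days (interaction adjusted p = 3.40e-04, limma). BBX28 changed 11.1-fold at 6.05 h in continuous light, COL2 9.62-fold at 1.48 h and COL9 7.33-fold at 15.6 h. SAUR genes, induced by auxin in growing tissue, were rhythmic in 21 of 39 in continuous light (adjusted p = 0.00852), at a mean peak of 6.09 h, and in 18 of 34 in long days (adjusted p = 0.0814). SAUR63, SAUR22 and SAUR20 changed 3.44-fold, 3.38-fold and 2.83-fold in continuous light.

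Genes of protein synthesis and breakdown were less rhythmic than others in 1 regime each. Ribosomal protein genes were rhythmic in 8 of 64 in long days (12.5% against 32.2% of other genes, Fisher's exact test, adjusted p = 0.00442). In continuous light they were rhythmic in 24 of 63 (38.1% against 28.6%, adjusted p = 0.329). There RPS5B and RPL5B (in a merged assembled gene) changed 1.44-fold and 1.39-fold. The rhythm differed between regimes for 0 of 64. Proteasome genes were rhythmic in 3 of 39 in continuous light (7.69% against 28.6%; adjusted p = 0.0142) and in 11 of 39 in long days (adjusted p = 0.912). The name pattern for 1 further group, sulfate assimilation, was corrected after its result was seen, since it had matched clock genes by a synonym.

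Plastid-encoded transcripts were higher in long days for 53 of 56 loci, with a median of 2.47 (log2), and the ratio of median plastid shares was 75.1. Mitochondrial transcripts were higher for 20 of 22 loci, with a median of 1.21, against 0.118 for nuclear loci. Since transcripts of both organelles rise, a difference in RNA selection between the libraries of the tables may explain part of the shift. Within continuous light the plastid share was 3.70 times higher in the second cycle than in the first, against 1.09 times in long days. Regime and table coincide and the library batches are unknown, so that an effect of light on organelle transcripts stays open and untested.

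Rhythmic usage in clock genes was set against an artefact of the log ratio, in which a minor isoform of constant share seems to move against its gene because of the pseudocount. This was first run as a count, in which 2 of 18 isoforms still passed after correction, both of RVE8, then as a median per gene, and is given here per isoform. A constant share would give 97.2% and 98.25% (continuous light) and 75.1%, 104%, 95.4% and 98.9% (long days) of the amplitude for the 6 calls of PRR9, which it can explain; a test of the share as a fraction passed for AT2G46790.3 and AT2G46790.4 in long days (adjusted p = 0.00678 over the list alone for each) but was dropped, since the gene lay at 0.117 and 0.129 FPKM at 17 and 20 h and such a share is a ratio of values near 0. It would give 0.538% for each isoform of GRP7, 18.5% and 9.94% for RVE8, 11.6% for LNK2's AT3G54500.5 and 5.80% for 1 assembled isoform of PRR7, which argues against it there, and it stays open for LNK2's AT3G54500.2 (30.7%), JMJD5 (33.6%) and the other isoforms of PRR7 (58.6% in continuous light, 62.3%, 57.7% and 41.55% in long days). RVE8's AT3G09600.1 went from an amplitude of 1.95 ± 0.30 to 1.60 ± 0.29 (log2; adjusted p = 0.0116 over the list alone), while GRP7's first isoform stayed at 0.60 and lost its call (adjusted p = 0.0654) as fewer isoforms of the list passed. Of the isoforms with at most 18.5%, AT3G09600.1 and AT3G54500.5 were not called rhythmic in their own level (limma, adjusted p = 0.693 and 0.993), and the others were.

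A free-running period longer than 24 h would shift peaks later in the second cycle of continuous light. Over 833 genes the median shift was -0.0534 h, from -0.244 to 0.0851 h when 1 library was left out, against -0.062 h over 1108 genes in long days (-0.415 to 0.274 h). These genes were chosen by a 24 h fit over both cycles, which favours genes whose peak did not move and can pull the median towards no shift. The sign in continuous light also depends on single libraries, so neither a longer period nor its absence was shown.

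A 24 h curve fitted the mean usage of all retained-intron isoforms in continuous light, with an amplitude of 0.0261 ± 0.0064 (log2) over 5551 isoforms and a peak at 8.58 h (permutation test over 16 library means, p = 0.00793, adjusted p = 0.0317). This mean was not corrected for a constant share seen through the pseudocount. Nor was it set against isoforms without a retained intron, so a rhythm of intron retention itself was not shown. The amplitude's upper bound of 0.0389 also lay under 0.1, the bound set beforehand for no rhythm. That bound was wrong, since it was set without knowing that the standard error would be as small as 0.0064. For distant 3' ends in continuous light, retained introns in long days and distant 3' ends in long days the adjusted p was 0.457, 0.457 and 0.480, and upper bounds of 0.0485, 0.0824 and 0.0761 leave room for a rhythm of that size.

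In 100 orders of the time labels, the real one included, 1 gave as many rhythmic genes as the real 5298 in continuous light (highest other 4) and 1 as many as 6034 in long days (527). For transcripts 1 was as large in each regime (highest others 121 and 4). In 100 splits into 6 and 10 libraries, 1 gave as many night calls as the real 852 and 3131 (highest others 216 and 116), and in 100 exchanges 1 gave as many level calls as 11851 (5680). Each of these counts was thus larger than in any other order, split or exchange drawn. Such draws take libraries as exchangeable, and for level calls they cannot tell regime from table. The splits into 6 and 10 do not keep neighbouring hours together, so they do not set the dark hours against another window of the day. The usage count in long days did not stand out, since 12 of 100 orders reached the real 2 (highest other 34). A count of 0 cannot be tested in this way, since every order reaches it, as did 100 of 100 for usage in continuous light (highest 5) and 100 exchanges for its difference (3).

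The share of FPKM in assembled transcripts was between 11.003 and 12.3% in the first cycle of long days and 14.4 to 15.7% in the second, and 10.03 to 11.7% over continuous light. Among isoforms short of the threshold, AT1G10650's first annotated isoform in continuous light had a usage amplitude of 2.37 (log2; adjusted p = 0.0731), and 2 assembled isoforms of AT4G24840, in a merged assembled gene, had 3.83 and 4.01 in long days (adjusted p = 0.0972 and 0.0818).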
